A study of Drosophila melanogaster with 3 samples.

How the data were processed

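Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos of 0 to 24 hours, male and female mixed, that carried a transgene for CG3163 fused to enhanced green fluorescent protein (eGFP). The chromatin was sheared by sonication to 200 to 800 bp and the fusion protein was recovered with an antibody against GFP, per the labels. The labels name 3 biological replicates in 1 group, so no comparison between groups was possible. The 3 replicates are numbered as in the labels.

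The authors deposited lists of peaks on 2 genome builds, dm3 and dm6. For each replicate there was a relaxed list, which keeps peaks and background as input for the irreproducible discovery rate (IDR) procedure, and there was a relaxed list for the pooled replicates. Per the deposited manifests, the pooled peaks were called on the alignments of the 3 replicates together against a control alignment. The list termed optimal was made from the replicate lists and the pooled list by an IDR threshold. The aligner, the peak caller and the threshold are not given in the sources used here. Each peak carries a signal value, which is the deposited peak height as the authors' caller gave it, on a scale that differs between lists. Signal was therefore used to describe, rank or filter peaks within a list. Each peak also carries a −log10 q-value, deposited by the authors, which had reached its ceiling of 4.01 in all 4446 optimal dm6 peaks and was not used for ranking. The summit offset deposited with each peak gave its position. The lists hold no read counts, so the depth of each sample is unknown. Confidence intervals of shares are Wilson 95% intervals, and those of odds ratios are normal 95% intervals of the log odds ratio. Both cover counting error only. The control alignment was not analysed here.

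All comparisons used the dm6 lists, because the reference was release 6 of the same genome. Gene models came from Ensembl release 115, annotation BDGP6.54, and no dm6 peak extended beyond the end of its chromosome. Coordinates were never converted between builds. The 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X were used, with 13945 protein-coding and 3951 non-coding genes and 23307 transcription start site (TSS) positions. Annotations of 5809 transposable elements, and pseudogenes, were left out. The 4446 optimal peaks were the 4446 strongest peaks of the pooled relaxed list. Background peaks were the 22929 pooled relaxed peaks with a summit over 1000 bp from any optimal summit. They come from the same libraries, but mappability was not measured for either set. Spread between replicates was taken from the 4446 strongest peaks of each replicate's own list, as mean ± SD with n = 3.

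A summit was called a promoter summit within 500 bp of a TSS. Other summits were placed in the first class that held them, in the order 5′ UTR, 3′ UTR, coding sequence, other exon, intron and intergenic. Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family of tests and a threshold of 0.05. Any p-value below 1e-300 was set to 1e-300 before adjustment. The unit of these tests is a peak or a gene. Neighbouring peaks and genes are not independent replicates, so the p-values describe these lists and not the spread between embryo collections. Promoter share was also compared with 10000 uniform placements of the summits within their chromosomes, and overlap of replicates with 1000 such placements. Summits within 250 bp of each other counted as shared. A gene counted as head-to-head when another protein-coding TSS on the opposite strand lay within 1000 bp upstream of its outermost TSS.

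Sequence matches were counted within 100 bp of a summit on either strand. The control windows had the same size and were centred 1000 bp to each side, and those within 500 bp of an optimal summit were left out. Where another set of peaks was tested, those within 500 bp of a summit of that set were left out instead. The 21 motifs were matched as exact consensus strings, with no weight matrix. All 8-mers, merged with their reverse complements, were tested by the one-sided form of Fisher's exact test.

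The 31 gene lists, the motifs, the main test of each comparison and the rule for named genes were fixed before the data were examined, as were most alternatives. Comparisons and alternatives added later are named as such where they are reported. The rule takes every gene with a TSS within 500 bp of the 25 strongest optimal peaks, with at most 2 genes per peak. It adds the 5 strongest peaks over 5 kb from any TSS, CG3163 itself, up to 4 members of each list that passed its test, and the 5 protein-coding genes with most optimal summits, at least 4 each, inside the gene or 500 bp upstream. A peak at a member of a gene family with near-identical copies is named as uncertain. Alternatives included other windows, stricter peak sets, other backgrounds and leaving out each replicate in turn.

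The code was tested on simulated data before use. In 20 random peak sets of 4446 peaks, 1 promoter test passed 0.05, as did 1 of 620 gene list tests and 1 of 420 motif tests after adjustment. With 30% of the summits of a random set moved to a TSS, the promoter share was 39.6% where 39.8% had been planted. An 8-mer planted in random windows ranked 1 of 32896, and without it 0 passed. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.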

Results

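Binding of CG3163, a Drosophila protein named only by its gene annotation number, was profiled by ChIP-seq in whole embryos that expressed it as an eGFP fusion. One group of 3 biological replicates was measured. The optimal dm6 list held 4446 peaks with a median width of 456 bp, and each relaxed dm6 list held 30000. The dm3 optimal list held 4737 peaks. Sequencing depth is unknown, because the lists give no read counts. In 99 cases an optimal interval carried a further summit, and 356 summits lay within 250 bp of the previous one, so neighbouring peaks are not independent.

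The first question was how far the replicates shared their binding sites. Of the 1111 strongest optimal peaks, 99.9% were among the 4446 strongest peaks of all 3 replicates, against 17.2% of the 1111 weakest. The weakest optimal peaks lie next to that limit of 4446, so much of this difference follows from the limit itself. The optimal peaks were also made from these same 3 replicates by an IDR threshold, so their agreement with each replicate is partly built in. In the relaxed lists of replicates 1, 2 and 3, 14, 35 and 14 optimal peaks had no summit within 250 bp. Of all optimal peaks, 3048, or 68.6%, were among the 4446 strongest of all 3 replicates. Between pairs of replicates 73.9% to 80.6% of the strongest peaks were shared, with a mean of 77.5% ± 2.28 (SD, n = 3 pairs). Uniform placement gave 1.56% to 1.60% on average and 2.27% at most. Spearman's rho of peak ranks across optimal peaks was 0.776 for replicates 1 and 2, 0.799 for 1 and 3 and 0.805 for 2 and 3. These are correlations across peaks within libraries, over peaks selected from the same replicates, with no p-value.

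The strongest peak lay at an internal start site of Svil, which encodes a supervillin-like actin-binding protein. Its summit was at dm6 3L:2466710, its signal 7711.58 and its rank 1, 4 and 1 in replicates 1, 2 and 3. The next peak, at 2L:7984269, lay 73 bp from a TSS of Snoo, a Ski/Sno family co-repressor, and 323 bp from CG7231. Peaks at both disconnected family zinc-finger genes were among the 25 strongest, with disco-r at X:16149261 ranked 3 and disco at X:16217103 ranked 14. In all, 17 of the 25 strongest peaks had a TSS within 500 bp, naming 20 genes. They included glec, which encodes gliolectin, at rank 5 and CG9171 at rank 6. The ecdysone receptor coactivator gene tai had rank 8, and CG42637 and the guanylyl cyclase gene Gyc76C shared a start site at rank 10. CG8036 and tRNA:Tyr-GTA-1-8 lay at the peak of rank 11. That tRNA gene belongs to a family of near-identical copies and is uncertain as a target. CG8306 had rank 12, the kinase gene fray 17, the transporter gene Mrp4 18 and CG5455 19. The zinc-finger gene shn, which acts in Dpp signalling, had rank 21, CG31523 22, Glyat 23 and dnr1 25. These 17 peaks ranked 34 or better in every replicate.

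Strong peaks also lay far from start sites. Over 5 kb from any TSS there were 403 optimal peaks, or 9.06%, against 20.3% of background peaks. The strongest of these lay at 3R:13208645, between genes, 109 bp from CG8483 and 5820 bp from its start site, with rank 13. Introns of Mnt, which encodes a bHLH partner of Max, held those at X:3695691 and X:3677007, with ranks 24 and 41. An intron of dnr1 held the peak at 2R:22569802, with rank 36, and an intron of the nuclear receptor gene Hr4 the one at X:1951880, with rank 42. At least 4 optimal summits fell in 202 protein-coding genes. Mnt held 19 over 29.9 kb and the Tousled-like kinase gene Tlk 19 over 69.8 kb. The forkhead gene CHES-1-like held 17, the kinase gene Raf 15 and the ecdysone-induced nuclear receptor gene Eip75B 13.

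The bithorax complex was chosen for description after its values had been seen. It lies on 3R, holds the Hox genes Ubx, abd-A and Abd-B, and carried 18 optimal summits over 326 kb, or 5.53 per 100 kb against 3.32 in the genome. Its strongest peaks lay in introns of lncRNA:iab8, between abd-A and Abd-B, at dm6 3R:16919209 (signal 4688.62, rank 15) and 3R:16899168 (signal 4584.4, rank 16). They ranked 12 to 17 in every replicate. Abd-B had a promoter summit at 3R:16934560 with rank 38, while the summit in Ubx, at 3R:16703055, had rank 2311.

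**Figure D1:**
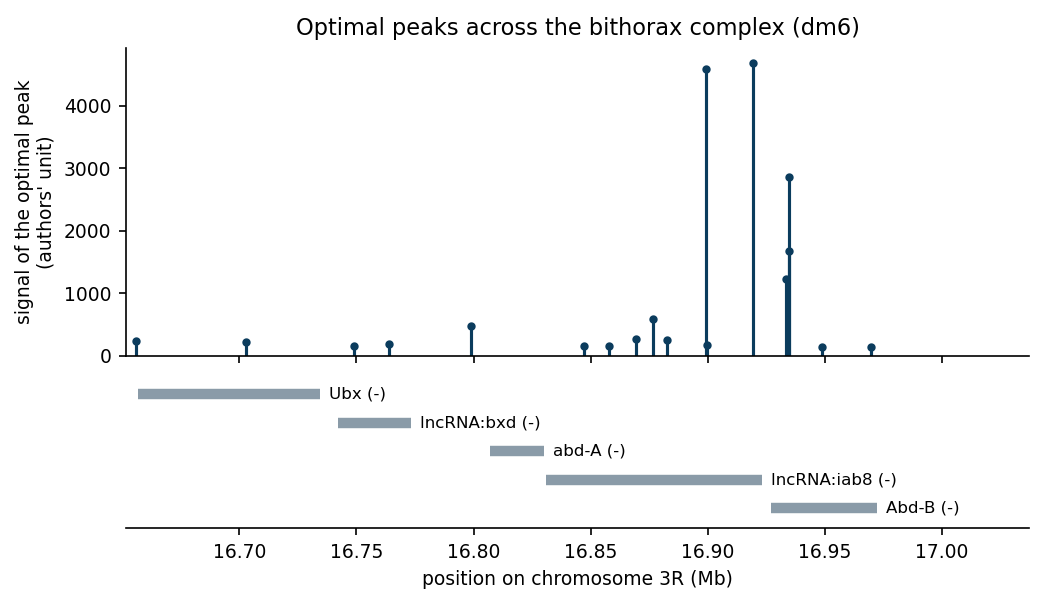
Signal of each optimal peak in the authors' unit (vertical axis) by summit position on dm6 3R (horizontal axis, Mb) across the bithorax complex, with genes as grey bars drawn to scale. The strongest peaks, with signal 4688.62 and 4584.4, lie in introns of lncRNA:iab8.

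Most of the optimal peaks lay at promoters. Of the 4446 summits 2718, or 61.1% (95% interval 59.7 to 62.6), were within 500 bp of a TSS. The share was 60.2% ± 1.42 (SD, n = 3) in the replicates' own strongest peaks. Background peaks reached 28.7%, an odds ratio of 3.90 with p = 1e-300, the floor for p-values (Fisher's exact test, two-sided). Uniform placement gave 13.5% and at most 15.5% (permutation p = 0.0001, the smallest that 10000 placements can give). Coding sequence held 22 optimal summits, or 0.495%, against 18.6% of background summits. In the replicates' own peaks the share was 1.09% ± 0.947 (SD, n = 3), and it was 0.551% without replicate 2, 1.32% without replicate 1 and 1.42% without replicate 3. The test covered 7 classes. The share of all optimal summits was also lower in 3′ UTRs (0.697% against 3.00%, adjusted exact p = 1.79e-23), in introns (26.1% against 34.1%, adjusted exact p = 1.53e-25) and between genes (9.69% against 13.5%, adjusted exact p = 1.02e-12). The class shares add up to the whole, so a higher promoter share lowers the others. Of the summits outside promoters, introns (1160 optimal, 7810 background) and intergenic DNA (431 and 3101) held a larger part in the optimal list. Coding sequence and 3′ UTRs still held a smaller part there. No test was run on summits outside promoters alone. Shares in 5′ UTRs (1.19% against 1.13%, adjusted exact p = 0.700) and other exons (0.697% against 0.925%, adjusted exact p = 0.189) did not pass the test. Promoter summits sat upstream of the start site, at a median of -54 bp (quartiles -142 and 10), and 72.0% were upstream. Those of background peaks had a median of 11 bp, and 47.0% were upstream. The medians of the replicates averaged -54.3 bp ± 4.73 (SD, n = 3).

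**Figure D2:**
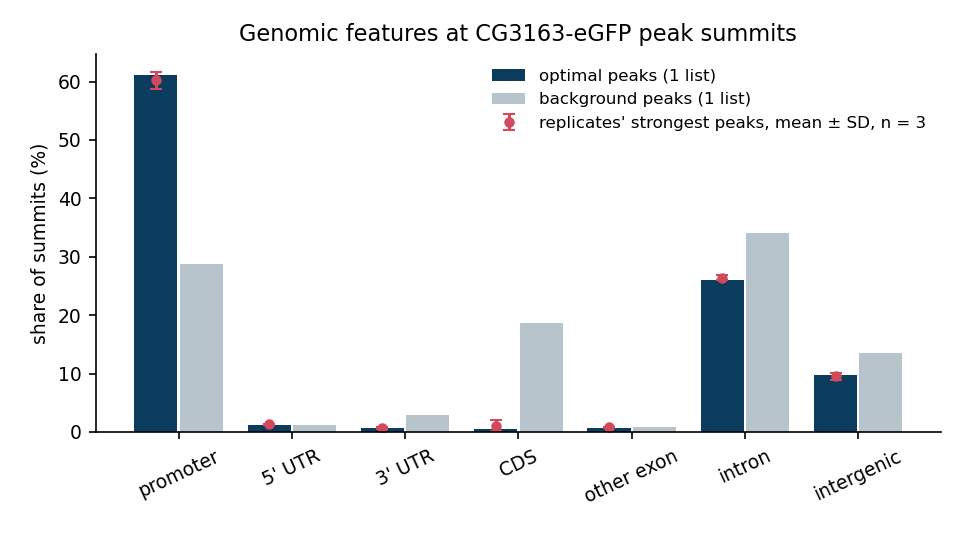
Share of peak summits (%, vertical axis) in each genomic class, for the optimal dm6 peaks (dark bars), the background peaks (grey bars) and the strongest peaks of the replicates (points, mean ± SD, n = 3). Promoters held 61.1% of optimal and 28.7% of background summits, and coding sequence 0.495% and 18.6%.

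Optimal summits lay within 500 bp of a TSS of 2787 protein-coding genes, or 19.99%, and of 262 non-coding genes. Head-to-head genes were bound more often: 1362 of 4650, or 29.3%, against 1425 of 9295 other genes, or 15.3%. The odds ratio was 2.29 (p = 9.50e-81, Fisher's exact test, two-sided). In the replicates' own peaks the shares were 28.1% ± 0.957 and 14.96% ± 0.271 (SD, n = 3). A head-to-head promoter holds 2 start sites, and 1 summit between them can count for both genes. Part or all of the gap may follow from this arrangement, so it is not a measure of preference per promoter. Among genes with a relaxed pooled summit the shares were closer, at 39.8% against 33.7%. The X chromosome carried 16.4% of optimal summits, which did not differ detectably from its 15.7% of protein-coding genes (exact p = 0.346) or its 16.8% of background peaks (exact p = 0.482). Its mean over the replicates' own peaks was 15.9% ± 0.390 (SD, n = 3). The promoter share was 62.8% in the 1111 strongest optimal peaks and 60.7% in the 1111 weakest (p = 0.315, Fisher's exact test, two-sided). The replicates differed here. The strongest of replicate 2 exceeded its weakest by 11.5 percentage points (exact p = 5.05e-08) and those of replicate 3 by 6.84 (exact p = 0.00115), while in replicate 1 the difference was -0.360 (exact p = 0.896).

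Of the 31 gene lists, 4 were bound more often and 4 less often than the other genes of their class after adjustment, and 13 had an unadjusted p under 0.05. Cytoplasmic ribosomal protein genes stood out, with peaks at 63 of 93, or 67.7%, against 19.7% of other genes. The odds ratio was 8.58 (adjusted exact p = 5.45e-22, Fisher's exact test, two-sided), and the share in the replicates' own peaks 64.5% ± 1.86 (SD, n = 3). RpS27 had the strongest peak of this group, at 3R:25247503 with rank 287, followed by RpL7 (353), RpL14 (422) and RpL23A (454). DNA replication and cell cycle genes had peaks at 18 of 38, or 47.4% (adjusted exact p = 0.000681), and at 45.6% ± 1.52 (SD, n = 3) in the replicates. They were led by CycE, the cyclin of S phase entry, at 2L:15748206 with rank 545, and by Cdk4 (675), the licensing factor gene dup (1040) and the E2F partner gene Dp (1063). Polycomb and Trithorax group genes had peaks at 13 of 29, or 44.8% (adjusted exact p = 0.00937), and at 43.7% ± 1.99 (SD, n = 3) in the replicates. They were led by the Mediator gene skd at 3L:21026474 with rank 556, then kis (755), Psc (773) and Sfmbt (1766). Tracheal and epidermal genes had peaks at 8 of 17, or 47.1% (adjusted exact p = 0.0420), and at 47.1% ± 5.88 (SD, n = 3) in the replicates. The snail family gene esg ranked 743, the EGF receptor ligand gene spi 846, the ETS repressor gene aop 982 and the Dpp receptor gene tkv 1502. The tracheal and epidermal call was lost in the peaks of replicate 2 (adjusted exact p = 0.0922). It was also lost with windows of 250 bp (41.2% against 17.0%, adjusted exact p = 0.0551) or 1000 bp (47.1% against 22.6%, adjusted exact p = 0.0849). The Polycomb and Trithorax call was lost at 250 bp (adjusted exact p = 0.0592). In the stronger 2223 optimal peaks the calls of the Polycomb and Trithorax list (20.7% against 10.4%, adjusted exact p = 0.300) and the replication and cell cycle list (23.7% against 10.4%, adjusted exact p = 0.0741) were lost. The tracheal and epidermal call was lost there too (29.4% against 10.4%, adjusted exact p = 0.101).

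Among the genes bound less often, 0 of 120 cuticle protein genes had an optimal peak (adjusted exact p = 4.85e-11). Chemosensory receptor genes had peaks at 2 of 179 (adjusted exact p = 1.19e-13), Ir60e and Ir60b, whose summits lay 324 and 453 bp from the start site. Seminal fluid and male-specific genes had a peak at 1 of 65, Sfp26Ad at 385 bp (adjusted exact p = 8.83e-05). The seminal fluid call was lost in the stronger 2223 peaks (1.54% against 10.5%, adjusted exact p = 0.0741). In the replicates the shares of these lists were 0.278% ± 0.481, 0.745% ± 0.323 and 2.05% ± 0.888 (SD, n = 3). The replication-dependent histone genes had 0 of 111 (adjusted exact p = 2.06e-10). No relaxed peak lay at any histone gene either, and these genes are near-identical copies in a repeated cluster, so they are uncertain. Restricting the test to genes with a relaxed pooled summit within 500 bp left 2 lists past the threshold, ribosomal proteins (73.3% against 36.02%, adjusted exact p = 1.68e-10) and cuticle proteins (0% against 36.6%, adjusted exact p = 0.000182). The other lists with a relaxed summit gave adjusted exact p = 0.495 for the cell cycle, Polycomb and Trithorax, tracheal and chemosensory lists and 0.673 for the seminal fluid list. Only 7.26% of chemosensory and 9.23% of seminal fluid genes had a relaxed summit, so few genes of these lists were left. Their shares were still lower than those of other genes, at 15.4% against 36.5% and 16.7% against 36.5%.

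The tissue lists of the embryo did not pass the test, apart from the tracheal and epidermal one. Peaks lay at 7 of 34 neural development genes, 4 of 26 muscle genes and 3 of 22 hemocyte, fat body and gut genes, each with an adjusted exact p of 0.844 or more. Segmentation genes had 5 of 27 and Hox genes 2 of 8. The Notch pathway (9 of 23), MADF and BESS domain proteins (4 of 7) and chorion, vitelline membrane and yolk genes (0 of 17) each had adjusted exact p = 0.0862. Insulator and architectural proteins had 7 of 18 (adjusted exact p = 0.153). Of other widely used genes, oxidative phosphorylation had peaks at 13 of 87, the proteasome at 7 of 48, mitochondrial ribosomal proteins at 20 of 73 and aminoacyl-tRNA synthetases at 8 of 33. RNA polymerase II machinery and Mediator had 18 of 63, splicing factors 5 of 25, nuclear pore proteins 4 of 21, autophagy genes 6 of 20, heat shock proteins 5 of 26 and dosage compensation 1 of 6. Among non-coding genes, peaks lay at 6 of 32 snRNA genes (adjusted exact p = 0.0580), 17 of 290 tRNA genes, 21 of 274 snoRNA genes and 9 of 260 microRNA genes (adjusted exact p = 0.0900). None of these lists passed the threshold in the optimal list with the 500 bp window. The insulator and architectural list did pass in the strongest peaks of each of the 3 replicates and in the 3048 peaks shared by all. The Notch list passed with windows of 250 and 1000 bp, in those 3048 peaks and in replicates 2 and 3. Other lists that passed under some setting were snRNA genes at 250 bp, MADF and BESS domain proteins at 1000 bp and in replicate 3, snoRNA genes at 1000 bp and mitochondrial ribosomal proteins in replicate 3. The MADF and BESS list includes CG3163 itself, whose nearest optimal summit lay 543 bp from its start site. In the optimal list it thus counted as bound at 1000 bp and not at 500 bp.

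**Figure D3:**
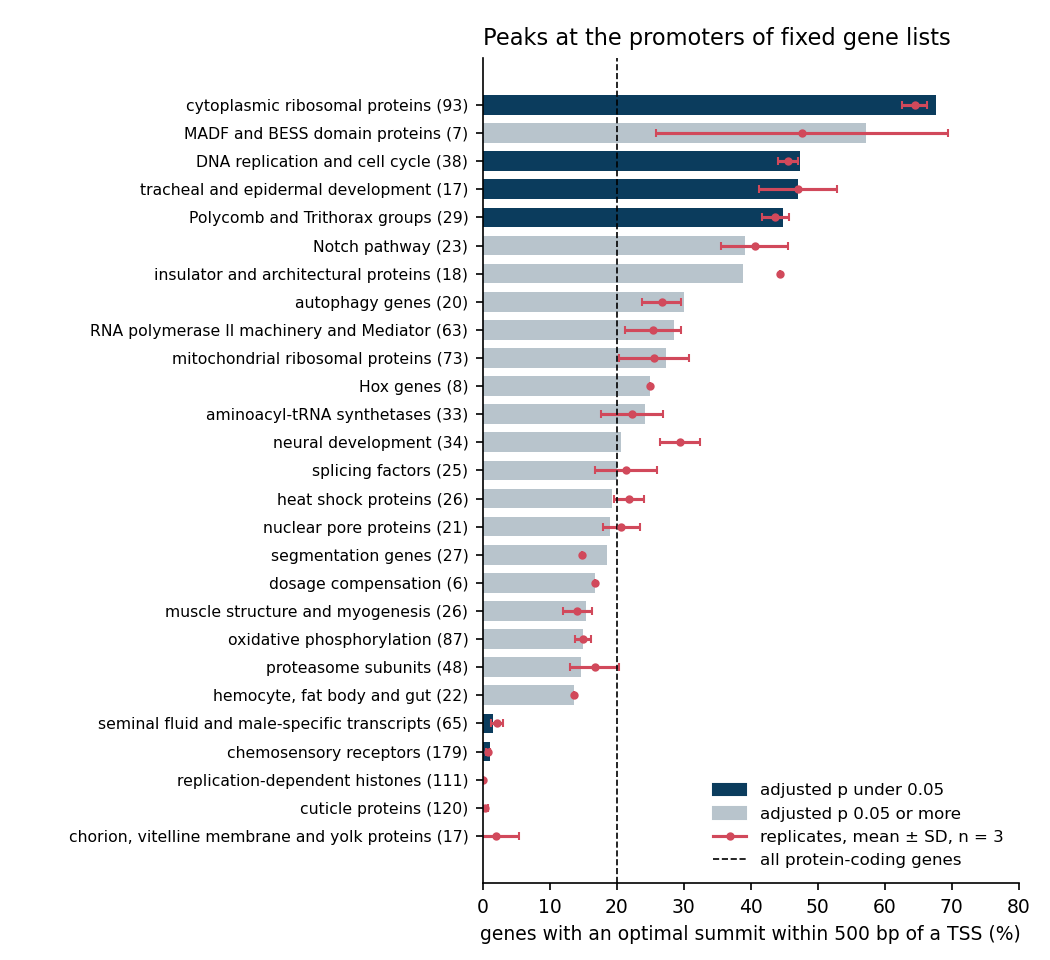
Share of genes (%, horizontal axis) with an optimal summit within 500 bp of a TSS for each protein-coding gene list (members in parentheses). Bars give the optimal list, dark where adjusted p was under 0.05, points the replicates (mean ± SD, n = 3) and the dashed line all protein-coding genes, 19.99%; ribosomal proteins reached 67.7%.

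The 8-mers most enriched at the summits were AG-rich. All 10 leading 8-mers fell in 1 group when linked by shared 6-mers. AAAGAGAG was present in 12.4% of peaks against 1.63% of control windows (adjusted exact p = 1.02e-129, one-sided) and AAGAGAGC in 9.85% against 0.800% (adjusted exact p = 9.61e-126). In the replicates' own peaks the shares were 12.05% ± 1.06 and 9.67% ± 0.741 (SD, n = 3). Of 32896 8-mers, 1199 passed the threshold, and 384 of them held AGAG, GAGA or their complements. The others were led by ATCGATAG (4.07% against 0.607%), TATCGATA (4.00% against 0.594%), CAACACTG (3.53% against 0.568%) and AGTGTGAC (2.86% against 0.478%). Mean GC content was 42.2% in peak windows and 42.9% in control windows.

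Of the 21 motifs, 9 were more frequent at summits than in the flanks and 3 less frequent. The GAGA repeat GAGAGAG was found in 14.8% of peaks against 3.27% (odds ratio 5.15, adjusted exact p = 2.87e-114, Fisher's exact test, two-sided). Core promoter motif 7 was found in 6.55% against 1.37% (adjusted exact p = 6.85e-51), the DNA replication-related element (DRE) in 4.00% against 0.594% (adjusted exact p = 2.39e-39), CTCF in 2.74% against 0.465% (adjusted exact p = 4.62e-25) and motif 1 in 1.57% against 0.207% (adjusted exact p = 9.45e-17). The BEAF-32 core CGATA (28.7% against 22.0%), motif 5 (1.71% against 0.426%), motif 6 (0.720% against 0.258%) and the initiator (19.5% against 17.7%, adjusted exact p = 0.0248) were also more frequent. CGATA lies within the DRE sequence TATCGATA, so DRE and BEAF-32 matches are not independent. The initiator call was lost with 1 summit per run of close summits (adjusted exact p = 0.0799), with a 50 bp window (adjusted exact p = 0.180) and in the stronger 2223 peaks (adjusted exact p = 0.0915). The motif 6 call was lost with a 50 bp window (adjusted exact p = 0.0743) and in the stronger 2223 peaks (adjusted exact p = 0.299). Bicoid (4.21% against 6.58%), Caudal (3.49% against 4.92%) and Stat92E (5.06% against 6.44%) sites were less frequent, though the Stat92E call was lost with a 50 bp window (adjusted exact p = 0.186). The other 9 motifs did not pass, among them Zelda (0.922% against 1.36%, adjusted exact p = 0.0564) and Grainyhead (1.10% against 0.723%, adjusted exact p = 0.0523). In the replicates' own peaks GAGA was found in 14.6% ± 1.23, motif 7 in 6.28% ± 0.103, DRE in 3.76% ± 0.115 and CTCF in 2.53% ± 0.182 (SD, n = 3). Against windows at promoters with no optimal summit, GAGA (3.11%) and CTCF (0.434%) stayed more frequent, motif 7 (6.09%, adjusted exact p = 0.354) and Caudal (3.6002%, adjusted exact p = 0.813) no longer differed detectably, and DRE (7.12% in those promoters), BEAF-32 (37.7%), the initiator (30.4%) and motifs 1 (3.74%), 5 (2.94%) and 6 (1.64%) were less frequent at the summits. Those control windows are centred on start sites and the peak windows on summits. With both centred on start sites, a comparison chosen after the data were seen, DRE (10.99% against 7.12%), BEAF-32 (46.1% against 37.7%) and motif 5 (4.15% against 2.94%) were more frequent at bound than at unbound promoters.

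Strong and weak peaks differed in sequence. This comparison of motifs by peak strength was not among those fixed before the data were examined. The GAGA repeat fell from 22.4% of the 1111 strongest peaks to 11.6% of the 1111 weakest (adjusted exact p = 2.78e-10). Some core promoter motifs and the BEAF-32 core went the other way. DRE rose from 1.62% to 5.49% (adjusted exact p = 5.79e-06), motif 1 from 0.540% to 2.70% (adjusted exact p = 0.000321), motif 7 from 4.05% to 7.92% (adjusted exact p = 0.000647) and BEAF-32 from 23.2% to 33.6% (adjusted exact p = 8.08e-07). Motifs 5 (1.62% and 2.07%, adjusted exact p = 0.831) and 6 (0.630% and 0.810%, adjusted exact p = 0.937) did not differ detectably. AAGAGAG, chosen after the 8-mers had been seen, was present in 56.4% (95% interval 51.8 to 60.9) of the 445 strongest peaks, in 10.1% (7.66 to 13.3) of the 444 weakest and in 3.18% of control windows. In the replicates' own peaks of those ranks the shares were 56.0% ± 3.64 and 11.9% ± 1.58 (SD, n = 3). Its matches were centred on the summit, with 2.04 per kb within 40 bp and 0.279 per kb at the outer ends of a profile that reached 500 bp.

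**Figure D4:**
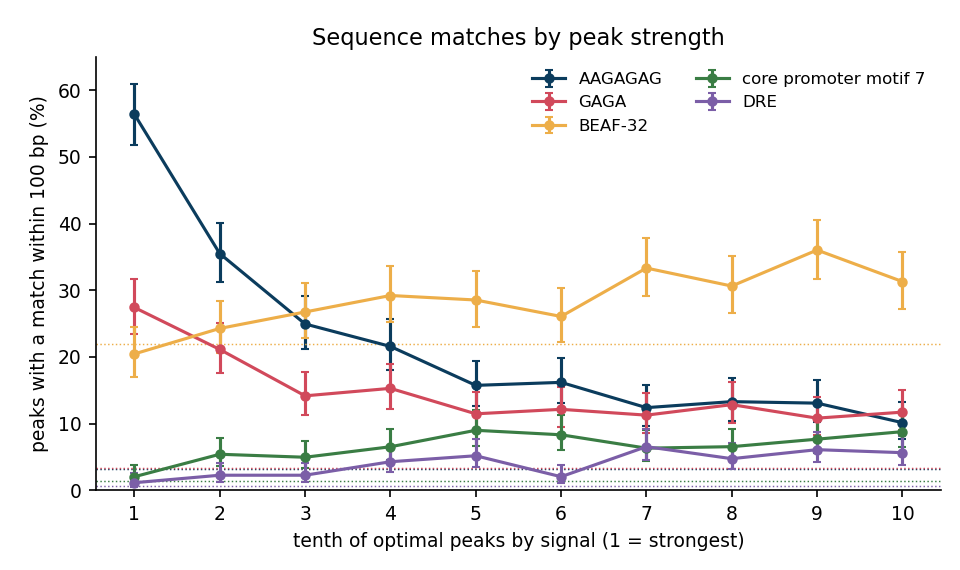
Share of optimal peaks (%, vertical axis) with a match within 100 bp of the summit in 10 groups of 444 or 445 peaks by signal (horizontal axis, 1 strongest), with Wilson 95% intervals and dotted lines for the control windows. AAGAGAG goes from 56.4% in the strongest group to 10.1% in the weakest, and GAGA, BEAF-32, core promoter motif 7 and DRE are drawn beside it.

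**Figure D5:**
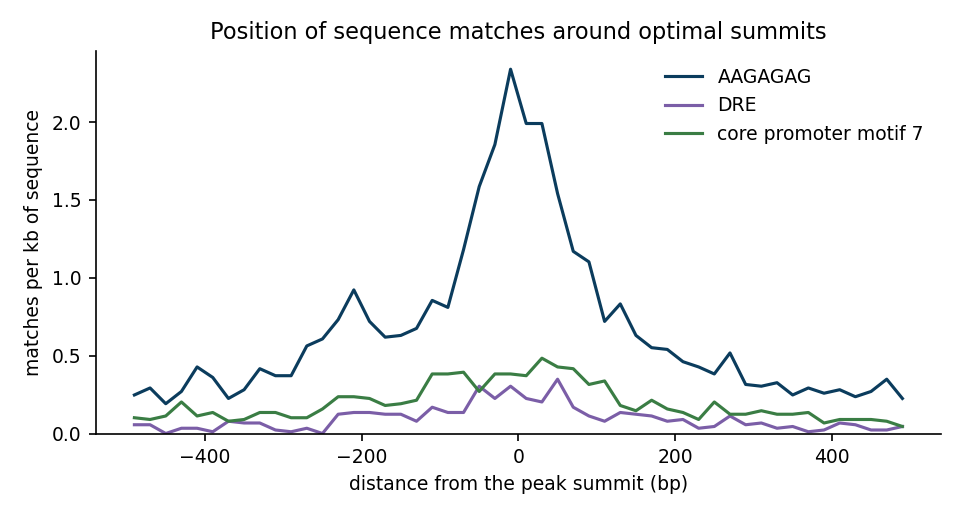
Matches per kb of sequence (vertical axis) in bins of 20 bp by distance from the optimal summit (horizontal axis, bp), for AAGAGAG, DRE and core promoter motif 7 over 4446 peaks. AAGAGAG averages 2.04 matches per kb within 40 bp of the summit.

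The CG3163 gene itself (FBgn0034961, dm6 2R:24029317-24030555, plus strand) had an optimal summit 543 bp upstream of its start site, at 2R:24028774, with signal 469 and rank 794. There were 3 optimal summits within 20 kb of the gene. The pooled relaxed list had 26 summits there, more than 91.0% of protein-coding genes, whose median was 14. The replicates had 23, 21 and 23, more than 84.2%, 83.3% and 83.6% of genes. Among the 459 genes with as many start sites nearby, to within 10%, a set chosen after the data were seen, the percentile was 71.0 in the pooled list (median 21) and 56.4, 56.4 and 55.3 in replicates 1, 2 and 3.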

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

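Signal was present in a part of the dm3 data that the comparisons above do not use. The dm3 optimal list held 4 peaks on the heterochromatic scaffold 3RHet, outside the 6 chromosome arms. The strongest had its summit at dm3 3RHet:2474198, with signal 1353.9 and rank 185 of 4737, and the others had ranks 676, 1562 and 3030. The peaks of rank 185 and 3030 start at the same base, so the 4 peaks mark 3 places. Coordinates were not converted, so whether these places lie within the dm6 arms used above was not examined. The dm3 relaxed lists held 25 to 83 peaks outside the arms.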

How the results depend on the processing

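The alternatives that average the replicates or leave one out for gene lists, genomic classes, head-to-head genes, 8-mers, the strength comparison, the summit position and the CG3163 locus, the summit position in the upper 2223 peaks, and those with 1 summit per run of close summits, were chosen after seeing the data. Promoter share kept its direction and its side of the threshold under every alternative, from 48.2% where whole peaks had to overlap a TSS to 71.2% with a 1000 bp window. Head-to-head genes did so too, from 14.6% against 8.38% in the upper 2223 peaks to 39.8% against 33.7% among genes with a relaxed summit, where the relative difference was smaller. Mean replicate overlap was 69.2% with summits within 100 bp, 68.1% with reciprocal overlap, 84.2% for 1000 peaks, 69.7% for double the number, and 75.8% to 80.1% without each replicate. Mean rho was 0.746 at 100 bp and 0.776 to 0.805 without each replicate. Placing introns first left 3 classes that differed in place of 5, by construction. The X share, never past the threshold, fell below that of genes in the upper 2223 peaks (14.8%) and without replicate 2 (15.7%; range without each replicate 15.7% to 16.1%); the cause was not tested. The upper 2223 peaks gave 4 gene lists in place of 8 and 533 8-mers in place of 1199, with fewer peaks tested. Genes with a relaxed summit gave 2 lists. There the share of comparison genes with a peak rose, for the cell cycle list from 19.9% to 36.4%. Members of that list had 47.4% and 48.6%, so its difference was smaller. That did not hold for the chemosensory list, with 1.12% against 20.2% of all genes and 15.4% against 36.5% of genes with a relaxed summit. The tracheal and epidermal list lost its call under 8 of its 9 alternatives, with adjusted exact p from 0.0282 to 0.495. These losses are not independent. Those in the mean of the replicates, without replicate 1 and without replicate 3 all take the largest p of the replicates included, that of replicate 2 (adjusted exact p = 0.0922). Replicates 1 and 3 each kept the call. Histone genes gave no value among genes with a relaxed summit, since none has one. Among single lists, motifs and classes 177 alternatives kept direction and call, 24 kept the direction and lost the call, and 6 reversed. With unbound promoters as control, 5 motifs were higher in place of 9, of which GAGA and CTCF were among the 9, and motif 7 and Caudal lost their calls. DRE (4.00%), BEAF-32 (28.7%), the initiator (19.5%) and motifs 1 (1.57%), 5 (1.71%) and 6 (0.720%) reversed; that control is centred on start sites, and with both sets so centred DRE, BEAF-32 and motif 5 were higher at bound promoters, while the initiator was still lower and motifs 1 and 6 did not pass the test, with causes not tested. The difference in promoter share between strong and weak peaks was -0.180 points with a 250 bp window and 3.24 to 9.18 without each replicate, past the threshold without replicate 1; the cause was not tested. The median summit moved to -73 bp in the upper 2223 peaks; the cause was not tested. CG3163 lay at percentile 93.9 within 10 kb, 83.7 in the mean of replicates and 83.5 to 83.9 without each replicate; the cause was not tested. The lists give no reads, so what depth limits is unknown.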

Other observations

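The AAGAGAG sequence, the comparisons of bound promoters, of distal peaks and of ribosomal protein peaks, and the tests on peaks without AAGAG, on housekeeping genes and on the CG3163 locus were chosen after the results had been seen. Centred on the start site, 2457 bound promoters of protein-coding genes were compared with 11055 unbound ones, in a family of 22 sequences. AAGAGAG (7.20% against 2.85%, adjusted exact p = 1.34e-20), motif 7 (14.1% against 6.09%, adjusted exact p = 6.46e-35), DRE (10.99% against 7.12%, adjusted exact p = 1.92e-09) and BEAF-32 (46.1% against 37.7%, adjusted exact p = 1.44e-13) were more frequent at bound promoters, and the TATA box less so (8.02% against 15.5%, adjusted exact p = 1.60e-23). Of 1280 optimal peaks over 1 kb from any TSS, 23.4% held AAGAGAG and 4.61% the CTCF motif, against 19.2% and 1.77% of the 2718 promoter peaks (adjusted exact p = 0.00709 and 3.57e-06). DRE was present in 0.156% and 6.36% (adjusted exact p = 8.19e-26). The 66 peaks at ribosomal protein promoters differed from other promoter peaks in 4 of 5 sequences tested: 4.55% held AAGAGAG against 19.6% (adjusted exact p = 0.00130), and 24.2% held DRE against 5.92% (adjusted exact p = 4.72e-06). BEAF-32 is among the 4, and every DRE match is also a BEAF-32 match, so these differences are not independent. Among the 500 strongest peaks AAGAGAG was present in 55.6%, AAGAGAGCG in 19.2% and TAAGAGAGC in 11.8%.

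Over all 4446 optimal peaks AAGAGAG had an odds ratio of 8.57 over the flanks (95% interval 7.41 to 9.91). Background peaks had an odds ratio over their own flanks of 1.63 (1.48 to 1.78), which argues against purine-rich DNA to the same degree in any called peak. They are the weaker pooled peaks, and AAGAGAG falls with strength within the optimal list too. A bias towards purine-rich DNA that grows with signal would give the same values, so it stays open. Promoter sequence in general is argued against by peaks over 1 kb from any TSS, with 6.71 (5.30 to 8.49). The flanks of background peaks and of these distal peaks were kept clear only of their own set. Some of them may therefore lie at other optimal summits. For GAGA repeats in general, GAGAG without AAGAG gave 0.172 (0.0936 to 0.317) between the strongest and weakest groups. That met the bound set beforehand but decides nothing, because leaving out AAGAG lowers the share wherever AAGAG is common. Among peaks with no AAGAG, GAGAG was present in 13 of 66 in the strongest group and 66 of 266 in the weakest. That gave 0.743 (0.381 to 1.45), against 11.5 (8.00 to 16.5) for AAGAGAG over all peaks of these groups. Few of the strongest peaks are left in that test, and GAGAG is a shorter sequence held within AAGAGAG. With AAGAG allowed, the repeat GAGAGAG did go with strength, at 27.4% of the strongest group and 11.7% of the weakest. A hypothesis is that CG3163, or a protein bound with it, may recognise this element. No other factor and no purified protein was measured, so direct and indirect recruitment stay open.

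The ribosomal protein genes had peaks with an odds ratio of 8.58. Among genes with a relaxed summit it was 4.86 (95% interval 3.01 to 7.86), so the presence of a relaxed summit did not account for it. That met the bound set beforehand but cannot decide on open promoters in general. A relaxed summit does not hold the degree of openness equal, and accessibility was not analysed here. Within strata of TSS number and head-to-head arrangement (Mantel-Haenszel) the odds ratio was 7.01 (4.33 to 11.3), which argues against extra start sites. Oxidative phosphorylation and proteasome genes together gave 0.694 (0.431 to 1.12), but both had low shares that were known when they were picked. The 8 housekeeping lists other than ribosomal proteins, pooled, gave 1.13 (0.877 to 1.45). As a set these genes were thus not bound detectably more often than other genes. Their shares too were known when they were pooled, so this describes the lists and is no independent test. Recovery of the most highly transcribed promoters by any antibody could still contribute, since expression and a control for the tag were not analysed here.

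The relaxed peaks around CG3163 were dense, which extra copies of the locus on the tagged transgene could cause. Among 459 genes with as many start sites nearby, to within 10%, CG3163 lay at percentile 56.4, 56.4 and 55.3 in replicates 1, 2 and 3, and at 71.0 in the pooled list, with 26 summits against a median of 21. Within 20 kb, this shows no gain that is visible as extra peaks, but it cannot exclude extra copies. The span counted included the gene, so longer matched genes had wider spans, and signal height was not compared. Within 10 kb the percentiles among all protein-coding genes were 94.1, 79.6 and 91.9 in replicates 1, 2 and 3. No comparison with matched genes was made at that distance. The number of start sites nearby may account for most of the density in the replicates, where the medians of the matched genes were 21, 20 and 22 against 23, 21 and 23 summits. No biological explanation beyond that number was tested.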
